A study of Mus musculus with 13 samples.

How the data were processed

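Small RNA libraries from 13 mouse samples were studied: 8 iPSC lines in 4 groups of 2, 4 somatic libraries and 1 ESC library. Per the labels, all libraries followed one protocol with gel selection of small RNAs, ligation of adapters to both ends and PCR. Per the submitters' processing notes, the genome build was mm9. The deposited files hold raw counts, 1 number of reads per distinct sequence (tag), with adapters already removed and no other normalization. The trimmer, aligner and filters are not given in the sources used here. Tags in the files were 18 to 44 nt long.

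Tags of 18 to 26 nt were matched with 0 mismatches, in sense, to the 1577 annotated miRNA hairpins of the mouse annotation on NCBIM37, the same assembly as mm9. Of these hairpins 550 carry a Mir name (470 names after copies were merged). A tag was given to the 5p or 3p arm by the side of the hairpin's middle, and tags matching arms of several names formed joint features. This gave 2149 features with a read, of which 884 were joint, holding 8.15% of miRNA reads. Hairpins without a Mir name held 0.296% of miRNA reads, apart from joint features that include a Mir name. Some known miRNAs have no hairpin of their name in this annotation (among them let-7e, miR-378a, miR-191, miR-100, miR-199b, miR-18a and miR-146a) and were not counted by name. Reads of some may have been counted under unnamed hairpins, such as AL808027.2, whose 3p arm shares tags with Mir199a-3p. Added 3′ bases were read from tags that match a hairpin only after 1 to 3 identical bases are removed.

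Libraries held 13479835 to 23279907 reads and 5578035 to 11799599 miRNA reads. The widest of 559 Wilson intervals of a share spanned 0.0828 percentage points. A floor of 3 counts per library was 2.54e-05 to 5.38e-05% of miRNA reads. Features absent from a class were bounded with that floor.

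File names read ASC, HSC and BSC where the titles read 2-APC, 2-HPC and 3-APC, and the titles and cell type labels were followed. Groups were taken from the sample titles before the data were examined, as were the comparisons, 15 miRNA lists, the rule for named miRNAs and most alternatives. Counts per feature were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. iPSC were compared with somatic libraries (8 against 4). In 5 contrasts of iPSC groups and along the number in the title (7 comparisons in all) the 8 iPSC libraries were fitted together. TMM factors were 1.13 to 1.58 in pluripotent and 0.476 to 0.592 in somatic libraries. DESeq2 1.42.0 was the other tool. Lists with at least 3 tested features were compared with all other features by camera of limma 3.58.1 on voom values, at a preset correlation of 0.01 and with an estimated one, and tested by fry. Composition was compared with exact permutation tests over all splits into 8 and 4. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the counting, intervals and plots.

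The lists were the miR-290, miR-302, miR-17, Dlk1-Dio3, Sfmbt2 and Fmr1-side clusters, the let-7 and miR-34 families, other imprinted loci, and haematopoietic, mesenchymal, epithelial, neural, striated muscle and endothelial, hepatic and endocrine miRNAs. A joint feature counted as a member only if all its names were members. Founder lists took features at least 8-fold higher at 50 CPM or more in 2-HPC than in every other somatic library, or the reverse. miRNAs named from iPSC against somatic libraries were the 12 with the largest change in each direction, past the threshold, with at least 100 CPM in the higher class and no overlap of libraries. In contrasts where fewer than 3 passed, the 3 with the lowest p were named as having missed it. Along the number in the title 6 were named per direction. The members of highest CPM were named for lists. The joint feature of Mirlet7a-5p and CT009696.1, the leading miRNAs of single libraries and the description of lines 37 and 42 were chosen after values were seen.

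The procedure was tested on simulated data with 200 changed features. For iPSC against somatic libraries (671 features) 33.3% of features changed by a log2 fold of 1.5 and 85.4% of those changed by 3 were called, and 4 of 489 unchanged ones. For 3-APC-iPSC against 1-MEF-iPSC (729 features) the shares were 22% and 78.4%, and 6 of 532. As many features were simulated higher as lower, so these shares do not cover errors of scaling in a comparison where most features change. Libraries were checked for duplicates, and Spearman correlations across features within iPSC groups were 0.875 to 0.933.

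Alternatives were DESeq2 size factors, total-count scaling, the DESeq2 test, no filter, shared tags left out, hairpins in place of arms, tags counted at least 2 times, a block for source, ESC counted with iPSC, the spread of the 2 compared groups alone, a 4-fold founder list and each library left out. Hairpins with a Mir name alone, tags of 21 to 23 nt alone, founder lists without Dlk1-Dio3 members, and list tests with total counts or with a library left out were added after seeing the data. Tags of 1% or more of a library that match no annotated small RNA were listed apart. No paired analysis was possible because the groups share no replicate numbers apart from the lone somatic and ESC libraries, but a block for source matched iPSC to their founder libraries.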

Results

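Small RNAs were sequenced from mouse cells of 3 classes. The first class held 8 lines of induced pluripotent stem cells (iPSC), 2 from each of 4 groups named 1-MEF-iPSC (lines 37 and 42), 2-APC-iPSC (lines 32 and 4), 2-HPC-iPSC (lines 16 and 18) and 3-APC-iPSC (lines 3 and 9). The second held 4 libraries of somatic cells: embryonic fibroblasts (1-MEF), adipose progenitor cells (2-APC and 3-APC) and haematopoietic progenitor cells (2-HPC), the last taken at passage 0 and the others at passage 1. The third was 1 library of R1 embryonic stem cells (ESC) of another strain, at passage 20 to 22. All iPSC lines were at passage 10 to 12, so passage differs between the classes throughout. The series title speaks of iPS cells reprogrammed in sequence and of reduced pluripotency, and the meaning of the leading number in each title is not stated in the labels. The labels do not say that lines came from separate cultures beyond their line numbers, so p-values here measure the spread between these samples, which may be technical.

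Depth ran from 13479835 reads (2-APC) to 23279907 (line 9). The other libraries held 23073445 (ESC), 18876602 (line 37), 18538959 (line 42), 15517152 (line 32), 16954686 (line 4), 17698680 (line 16), 17258434 (line 18), 18477203 (line 3), 16209528 (1-MEF), 16576453 (2-HPC) and 14974778 (3-APC) reads. Between 5578035 and 11799599 reads per library matched an annotated miRNA hairpin. Values are scaled miRNA read counts (CPM of edgeR, with library sizes scaled by TMM), given as mean ± SD with n = 8 iPSC and n = 4 somatic libraries unless stated. Intervals are 95% Wilson intervals. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. A floor of 3 counts per library stood at 0.2005 to 0.685 CPM.

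The somatic and pluripotent libraries differed in their whole make-up before any single miRNA was compared. Tags of 21 to 23 nt, the length of mature miRNAs, made up 85.0% ± 2.67 (SD, n = 4) of somatic reads and 46.8% ± 5.10 (SD, n = 8) of iPSC reads. Tags of 25 to 31 nt made up 3.78% ± 1.42 and 21.2% ± 4.90. Reads matching a miRNA hairpin made up 69.6% ± 2.15 and 44.3% ± 7.27. Each of these 3 differences had an exact two-sided permutation p of 0.00202, the smallest that all splits into 8 and 4 allow (adjusted p 0.00354 over 7 tests), and no library of a class overlapped the other class. When each distinct tag was counted once, the differences were -6.57 percentage points in 21 to 23 nt tags, 5.99 in 25 to 31 nt tags and -1.04 in miRNA hairpin tags. ESC held 47.8% tags of 21 to 23 nt, 24.5% of 25 to 31 nt and 36.5% miRNA reads. Part of the iPSC share at 25 to 31 nt was sequence without a match in the genome. In line 3 a 28 nt tag of this kind took 7.88% of reads and a 27 nt tag 2.78%. In line 37 they took 0.0744 and 0.0405%, and in somatic libraries 0 reads were counted. Among tags of 10 or more reads, 59.4 to 79.3% of iPSC and 73.8 to 81.4% of somatic reads matched the genome.

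**Figure D1:**
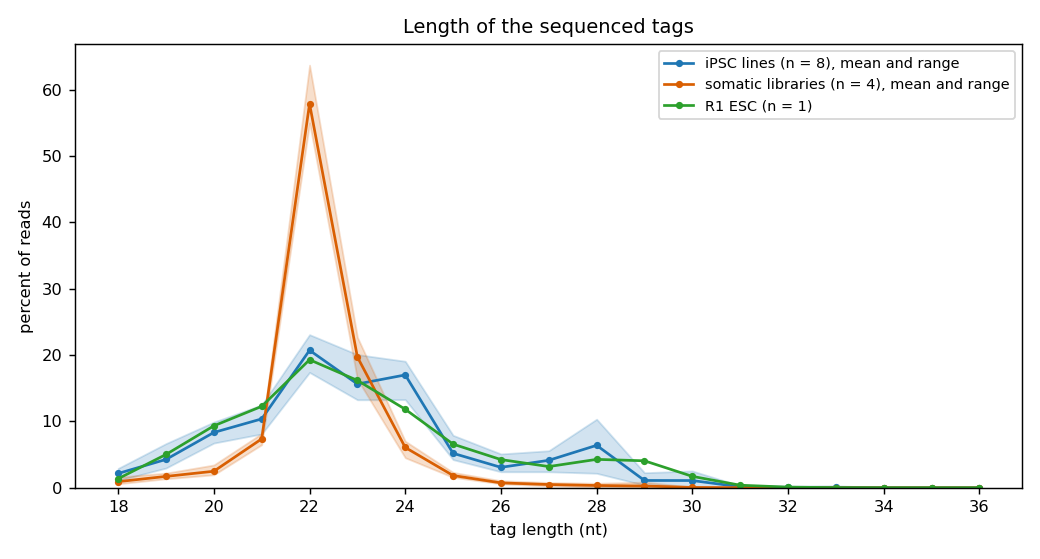
Share of all reads (%, vertical axis) at each tag length (nt, horizontal axis) as the mean and range of 8 iPSC and 4 somatic libraries and in ESC. Tags of 21 to 23 nt held 85.0% of somatic and 46.8% of iPSC reads on average.

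Added 3′ bases also differed between the classes. Bases added after transcription can mark a miRNA or its precursor for decay or for processing, and let-7 precursors receive added U in stem cells. Tags with 1 to 3 added A made up 14.0% ± 4.74 of somatic and 5.73% ± 0.638 of iPSC miRNA tags (exact permutation p 0.00202, adjusted p 0.00354). For let-7 tags alone the shares with added A were 17.0% ± 5.63 and 10.0% ± 1.48 (exact permutation p 0.0121, adjusted p 0.0121). Added T was more common in iPSC over all miRNAs, 4.37% ± 0.977 against 2.32% ± 0.901 (exact permutation p 0.0121, adjusted p 0.0121). Among let-7 tags the counted share was lower, 0.472% ± 0.130 against 0.945% ± 0.350 (exact permutation p 0.00808, adjusted p 0.0113). A base equal to the next base of the hairpin was counted as part of the hairpin, so added T can be missed. The let-7 difference therefore does not show whether let-7 received less U in iPSC. ESC gave 5.61% and 11.2% for added A and 4.21% and 0.615% for added T, over all miRNAs and let-7. The adapter begins with U, so a base left by trimming would count as an added T. The shares pool many miRNAs, and their mix differed between the classes. The let-7 list, for example, took 55.0% of somatic and 2.74% of iPSC miRNA reads. Which miRNAs were abundant may therefore bear on these differences, and shares per miRNA were not compared.

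The most common 3′ end of a miRNA divided the somatic from the pluripotent libraries. Among tag starts with at least 1000 reads in both libraries of a pair, the most common tag ended at the same base in 96.0% of starts between iPSC libraries (28 pairs) and in 92.4% between fibroblast and adipose libraries (3 pairs). The share was 58.0% between iPSC and fibroblast or adipose libraries (24 pairs, 52.3 to 67.6%). The haematopoietic library, a different cell type, matched the fibroblast and adipose libraries in 86.4% (3 pairs) and the iPSC libraries in 59.7% (8 pairs). All somatic libraries stand on one side of this division and all pluripotent ones on the other, so library set, passage and cell class cannot be told apart.

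The first comparison asked which miRNAs differ between iPSC and the somatic cells. The miR-290 cluster, which promotes the short cell cycle of embryonic stem cells, took 5.05% ± 1.20 of iPSC miRNA reads (3.98 to 7.29%) and 3.41e-05% of somatic ones, and all 14 tested features were higher. Mir292-5p stood at 16499.7 ± 4501 CPM in iPSC with 0 somatic reads, at least 31323-fold higher. The miR-302 cluster, which acts with the miR-290 cluster in pluripotent cells, took 0.529% ± 0.385 against 0 reads, and all 8 features were higher. The listed features of the let-7 family, which drives differentiation, took 2.74% ± 1.43 of iPSC and 55.0% ± 8.55 of somatic miRNA reads, and all 13 features were lower. The epithelial list (the miR-200 and miR-183 groups) took 45.4% ± 10.1 against 0.00806% ± 0.00314, with all 17 features higher. Of these the miR-200 group holds cells in an epithelial state, but most reads came from the miR-183 group. In line 42 Mir182-5p took 46.6% and Mir183-5p 14.1% of miRNA reads, out of 61.2% for the list. In line 18 they took 22.9 and 7.38% out of 30.7%.

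**Figure D2:**
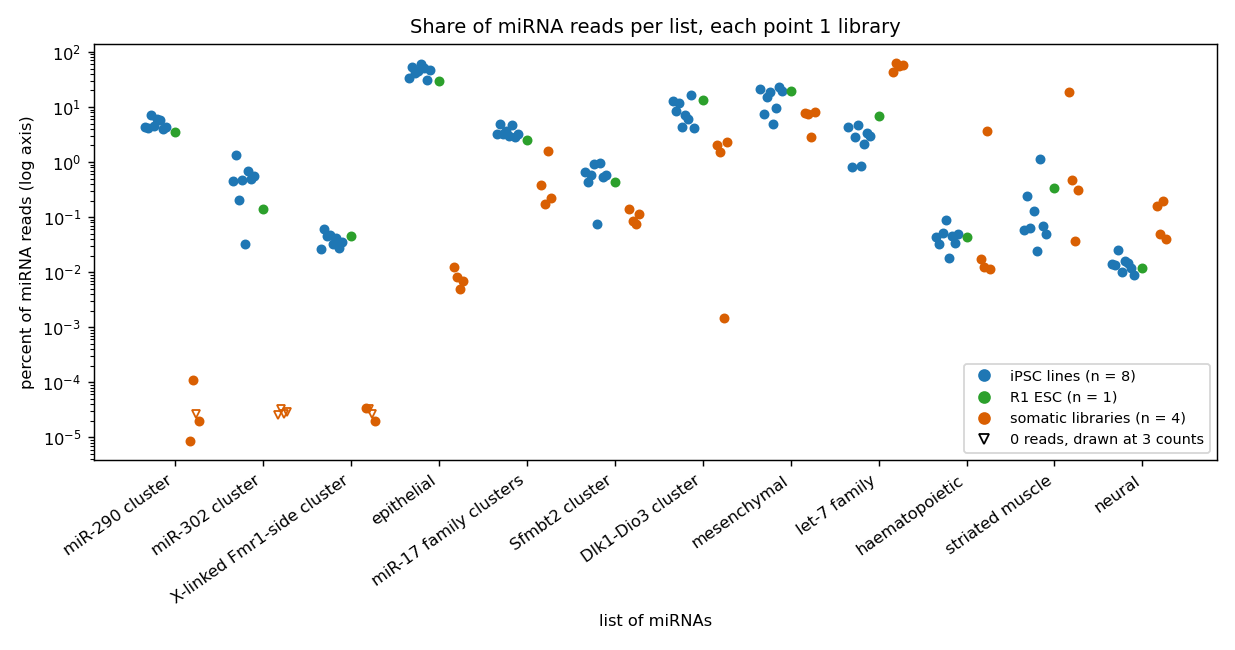
Share of miRNA reads (%, logarithmic vertical axis) of fixed miRNA lists in each library, with 1 point per library of iPSC, somatic cells or ESC and triangles at 3 counts where a library held 0 reads. The let-7 list held 55.0% of somatic and 2.74% of iPSC miRNA reads on average, and the epithelial list 45.4% of iPSC reads.

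Within those groups a few miRNAs carried most reads. Mir182-5p (chromosome 6, 30115918 to 30115992) stood at 259652 ± 77426 CPM in iPSC and 94.996 ± 68.1 in somatic libraries (log2 fold change 11.31, SE 1.29, edgeR adjusted p 3.28e-06). It took 22.9 to 46.6% of iPSC miRNA reads. Mir200c-3p changed by 8.14 (SE 1.20, adjusted p 3.08e-05). Mirlet7f-5p fell from 379712 to 9648 ± 4581 CPM (log2 fold change -5.44, SE 0.505, adjusted p 4.06e-07). The joint feature of Mirlet7a-5p and the unnamed hairpin CT009696.1 stands outside the let-7 list because its tags match both. The let-7 shares of miRNA reads given here leave it out and are too low for the whole family. It took 11.5 to 16.2% of somatic miRNA reads and changed by -5.36 (SE 0.517).

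The 12 largest increases by the fixed rule included 11 products of the miR-290 and miR-302 clusters. All positions are on build NCBIM37. Mir292-5p (chromosome 7, 3219190 to 3219271) changed by a fitted 20.21 (SE 0.947, edgeR adjusted p 3.58e-08), and Mir302b-3p (chromosome 3, 127248146 to 127248219) by 17.85 (SE 1.72, adjusted p 3.24e-06). Fitted changes against 0 reads depend on the prior count. As bounds, Mir302b-3p was at least 5957-fold higher (3138 ± 2298 CPM), Mir294-3p at least 2709-fold (1427 ± 380), Mir291a-3p at least 2500-fold (1317 ± 969), Mir302a-5p at least 1176-fold (619 ± 443) and Mir291b-5p at least 794-fold (418 ± 204). Mir293-3p stood at 6449 ± 2976 CPM against 2 somatic reads in all, a ratio of 75417 with a counting interval of 20878 to 622739. Mir295-3p stood at 5715 ± 3017 CPM against 3 reads (ratio 44560, 15248 to 216077) and Mir293-5p at 2911 ± 1642 CPM against 1 read (ratio 68091, 12221 to 2689450). Mir291a-5p stood at 1637 ± 697 CPM against 1 read (ratio 38277, 6869.97 to 1511860) and Mir292-3p at 1239 ± 435 CPM against 2 reads (ratio 14485, 4009.77 to 119605). Mir135b-3p (chromosome 1, 134094665 to 134094761), a member of no list, was at least 311-fold higher (164 ± 48.6 CPM).

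The 12 largest decreases were chosen by the same rule. Mir223-3p (chromosome X, 93438156 to 93438265), a miRNA of myeloid cells, changed by -16.68 (SE 2.29, edgeR adjusted p 1.66e-05), or -7.60 without 2-HPC. It stood at 40038.5 CPM in 2-HPC, 8.62 to 32.2 CPM in the other somatic libraries and 0 to 0.193 CPM in iPSC, and DESeq2 gave it no p. Mir222-3p, which restrains a cell cycle inhibitor, fell from 5291 ± 2485 to 24.8 ± 14.9 CPM (-7.89). Mirlet7b-5p fell by 6.75 and Mirlet7i-5p by 6.71 on the log2 scale. The joint feature of Mir27a-3p and Mir27b-3p fell from 761 ± 212 to 1.38 ± 0.760 CPM (-9.22). The others were the joint feature of Mir103-3p and Mir107-3p (-10.22), Mir107-3p alone (-8.86), Mir193-3p (-7.87), Mir23b-5p (-7.87), Mir322-3p (-7.36), a joint Mirlet7a-5p feature with 2 other names (-7.12) and Mir29c-3p (-6.68). Joint features hold only tags that do not tell their names apart, which may be shortened forms. Because 3′ ends differed between the classes, the fall of a joint feature need not be that of the whole miRNA.

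Other groups of related miRNAs also moved. The miR-17 family clusters, which speed proliferation, had 13 features higher and 2 lower of 20, with Mir20b-5p at 3456 ± 1328 CPM against 5.55 ± 11.1 (9.20, SE 1.84) and Mir25-3p lower (-2.04, or -0.79 without 2-HPC and -0.72 with adjusted p 0.248 under total-count scaling). Without 2-HPC Mir20b-5p had 18.01. The Sfmbt2 cluster, inside an imprinted gene on chromosome 2 (10292137 to 10516880), had 36 higher and 3 lower of 51, among them Mir467d-5p (3.05), whereas Mir669c-5p stood at 0.76 (SE 0.609, adjusted p 0.272). The X-linked cluster beside Fmr1, known from germ cells, had all 12 features higher, with Mir878-5p at least 188-fold and Mir871-3p at least 102-fold higher. Of 6 features on the list of endothelial, hepatic and endocrine miRNAs 4 were higher, with Mir126-3p at 7.69 and Mir7-5p at 5.14.

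Lists of somatic lineages mostly went the other way. On the mesenchymal list 20 of 32 features were lower (12 lower and 4 higher with total-count scaling), for example Mir29a-3p (-6.45, SE 0.551) and Mir10a-5p (-2.02, SE 0.487, or -0.60 with adjusted p 0.303 under total-count scaling). Its share of miRNA reads was nonetheless 15.0% ± 6.91 in iPSC and 6.58% ± 2.52 in somatic libraries, and Mir143-3p and Mir21-5p were its most abundant members in iPSC. Mir143-3p, a miRNA of smooth muscle and mesenchyme, took 2.66 to 10.8% of iPSC and 0.00107 to 0.890% of somatic miRNA reads (2.25, SE 0.987, edgeR adjusted p 0.0516, DESeq2 adjusted p 0.00829). Mir21-5p took 1.86 to 11.5% of iPSC reads (-0.17, SE 0.578, adjusted p 0.797). All 5 striated muscle features were lower, but only 3 without 1-MEF, where Mir206-3p went from -5.55 to -1.55 (adjusted p 0.279). Also lower were 7 of 9 neural features (5 with total-count scaling, Mir128-3p -4.63), 6 of 10 haematopoietic features (4 lower and 5 higher without 2-HPC, Mir142-5p -4.67 but 2.06 without 2-HPC, Mir142-3p -2.11 with adjusted p 0.174) and 6 of 8 of the miR-34 family, which acts downstream of p53 (3 with total-count scaling, Mir34b-5p -5.13, Mir34c-5p 0.09 with adjusted p 0.934).

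Imprinted clusters were mixed. The Dlk1-Dio3 cluster, whose maternal expression accompanies full developmental potential of iPSC, had 15 features higher and 30 lower of 82 (15 and 29 adjusted over the list alone), and its median was -1.20 but 0.26 with total-count scaling, where 22 were higher and 22 lower, and -0.76 without 1-MEF. Its most abundant members were higher, with Mir379-5p at 28341 ± 14520 against 1254 ± 863 CPM (4.37, SE 1.22, edgeR adjusted p 0.00498) and Mir134-5p at 3.62 (SE 1.12), and Mir127-3p stood at 0.40 (adjusted p 0.703). Its share of miRNA reads was 8.97% ± 4.44 in iPSC, 1.47% ± 1.04 in somatic libraries and 0.00144% in 2-HPC, and without 2-HPC the list passed (median -1.60, adjusted p 3.22e-05, 16 features higher and 47 lower). The list of other imprinted loci had 1 feature higher and 3 lower of 7 (Mir335-3p 6.68, or 10.22 without 1-MEF, Mir483-5p -7.70, or -2.13 without 1-MEF, and Mir298-5p -3.18, or -1.80 with total-count scaling), with a median of -0.51 that became 0.86 with total-count scaling and ranged from -1.70 (without 2-APC) to -0.43 (without line 42) with a library left out.

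Over all features edgeR called 517 of 709 at a false discovery rate of 0.05, 299 higher and 218 lower in iPSC (57.8% higher, median log2 fold change 0.56). DESeq2 called 504 (308 higher, 196 lower). With total-count scaling the split was 368 higher and 147 lower (71.5% higher) and the median of all features rose to 1.90, and with DESeq2 size factors it was 0.69. The higher and lower counts are therefore relative to the scaling. No iPSC library overlapped any somatic one in 358 features, 50.5% of those tested against 0.404% by chance, and 355 of these were called. For every list but Dlk1-Dio3 the counts adjusted over the list alone equalled those over all features.

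limma's camera compared each of the 15 lists with all other features at a preset correlation of 0.01, and 10 passed. Lists passing upward were miR-290 (median 14.80, or 11.35 with bounded members, adjusted p 7.62e-09, 0.148 with an estimated correlation), the Fmr1-side cluster (8.64, or 6.21, 8.31e-06, 0.220 with an estimated correlation) and the epithelial list (6.00, 9.11e-05, 0.148 with an estimated correlation). The others upward were miR-302 (11.38, or 6.09, 0.000832), Sfmbt2 (2.79, or 2.54, 0.00793) and miR-17 (3.32, 0.0181), with adjusted p of 0.492, 0.527 and 0.527 with an estimated correlation. Lists passing downward were let-7 (-5.73, 1.45e-08), mesenchymal (-2.23, 9.11e-05), neural (-3.17, 0.0231) and striated muscle (-6.96, 0.0372), with adjusted p of 0.148, 0.527, 0.148 and 0.527 with an estimated correlation. With total-count scaling the mesenchymal median was -0.73 and the neural one -1.78. The fry test, which asks whether a set's genes move on balance one way, passed 11 lists. The muscle median was -2.82 (adjusted p 0.0408) without 1-MEF, and -6.96 (adjusted p 0.126) without line 4, where only 3 features could be tested.

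The remaining 5 lists did not pass with all libraries. The miR-34 family had a median of -2.24 (adjusted p 0.0508) and passed without line 42 (-2.10, 0.0494) or without 2-HPC (-2.63, 0.00433). The haematopoietic list had a median of -4.68 (adjusted p 0.128), passed without 3-APC (-5.08, 0.0281) and stood at 0.72 without 2-HPC. The endothelial, hepatic and endocrine list (3.12, adjusted p 0.307), the other imprinted loci (-0.51, 0.307) and Dlk1-Dio3 (-1.20, 0.348) were the others. With an estimated correlation the epithelial list had adjusted p 0.0224 without 3-APC.

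The somatic libraries, with 1 library per title, were described without a test. Mirlet7f-5p led in 1-MEF (18.9% of miRNA reads, 18.8646 to 18.9092) and in 2-HPC (34.4%), and Mirlet7c-5p led in 2-APC (26.7%) and 3-APC (25.3%). The fibroblast library carried miRNAs of skeletal muscle, with Mir206-3p at 13.4% (13.401 to 13.4399) and Mir1a-3p at 4.88%. Its muscle list took 18.4% of miRNA reads. The haematopoietic library carried Mir223-3p at 2.24% (2.2357 to 2.25301), Mir451-5p at 12168 CPM, Mir142-5p at 6349 CPM and Mir144-3p at 356 CPM, which mark myeloid and red cells. Its haematopoietic list took 3.74% of miRNA reads.

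The iPSC groups were then compared by title, to ask whether the cell of origin or the number in the title leaves a mark. No single miRNA passed in any contrast with edgeR, so lists and the lines behind them carry the description. Lines 37 and 42 of 1-MEF-iPSC, the reference of 3 contrasts, stood far apart. Line 37 held 4.29% let-7, 21.7% mesenchymal and 33.8% epithelial reads, and line 42 held 0.844%, 4.93% and 61.2%. The miR-302 cluster took 0.445% in line 37 and 0.0326% in line 42, and the Sfmbt2 cluster 0.647% and 0.0758%. Line 4 held 1.12% striated muscle reads, mostly Mir206-3p, and its group mean was 4801 CPM against 215, 376 and 501 CPM in 1-MEF-iPSC, 2-HPC-iPSC and 3-APC-iPSC. Across the 8 lines the let-7 and mesenchymal totals went together on the log2 scale (Pearson r 0.922, exact permutation p 0.00186, adjusted p 0.00372, and Spearman rho 0.857, exact permutation p 0.0107, adjusted p 0.0107, over 40320 pairings). Without lines 42 and 32, the farthest from the median, r was 0.782 (n = 6), and this was the only relation computed (1 relation).

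The Dlk1-Dio3 cluster (chromosome 12, between Dlk1 at 110691033 to 110701546 and Dio3 at 111517278 to 111519307) was lowest in 3-APC-iPSC. Its total was 30116 and 31123 CPM in lines 3 and 9, 46721 to 62447 in 2-APC-iPSC, 64350 to 100222 in 1-MEF-iPSC, 75914.5 to 129778 in 2-HPC-iPSC and 116782 in ESC. Mean CPM of Mir379-5p in 1-MEF-iPSC, 2-APC-iPSC, 2-HPC-iPSC and 3-APC-iPSC (n = 2 each) was 35982, 23030, 41063 and 13289, and that of Mir541-5p was 18360, 12306, 20727 and 5729. In 3-APC-iPSC against 1-MEF-iPSC 80 of 83 features were negative (median -1.30, camera adjusted p 9.28e-39, 0.0623 with an estimated correlation, fry 0.0394), and 32 were lower when adjusted over the list alone against 0 over all features. The median was -0.81 without line 37 and -1.11 with total-count scaling. The mesenchymal list moved with the cluster in 2-HPC-iPSC against 2-APC-iPSC (median 1.82) and in 2-APC-iPSC against 1-MEF-iPSC (-1.58), and against it in 3-APC-iPSC against 2-APC-iPSC (1.39).

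The cluster's other contrasts went the same way around. 2-HPC-iPSC stood above 2-APC-iPSC in all 83 features (median 1.13, camera adjusted p 3.49e-24, 0.163 with an estimated correlation, fry 0.0705), with Mir134-5p at 1.53 (SE 0.442, edgeR adjusted p 0.269). 3-APC-iPSC stood below 2-APC-iPSC in 68 features (median -0.79, camera adjusted p 1.69e-12, 0.257 with an estimated correlation), or -0.51 without line 32, with 1 feature lower when adjusted over the list alone. 2-APC-iPSC stood below 1-MEF-iPSC in 74 (median -0.65, adjusted p 1.59e-08, 0.379 with an estimated correlation), or -0.27 without line 37. 2-HPC-iPSC stood above 1-MEF-iPSC in 68 (median 0.44, adjusted p 4.23e-06, 0.522 with an estimated correlation), with 0.27 (adjusted p 0.0612) without line 18, 0.79 without line 37 and 0.28 without line 42. Against the number in the title 79 of 82 features were negative (median -0.64 per step, adjusted p 1.43e-31, 0.640 with an estimated correlation).

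**Figure D3:**
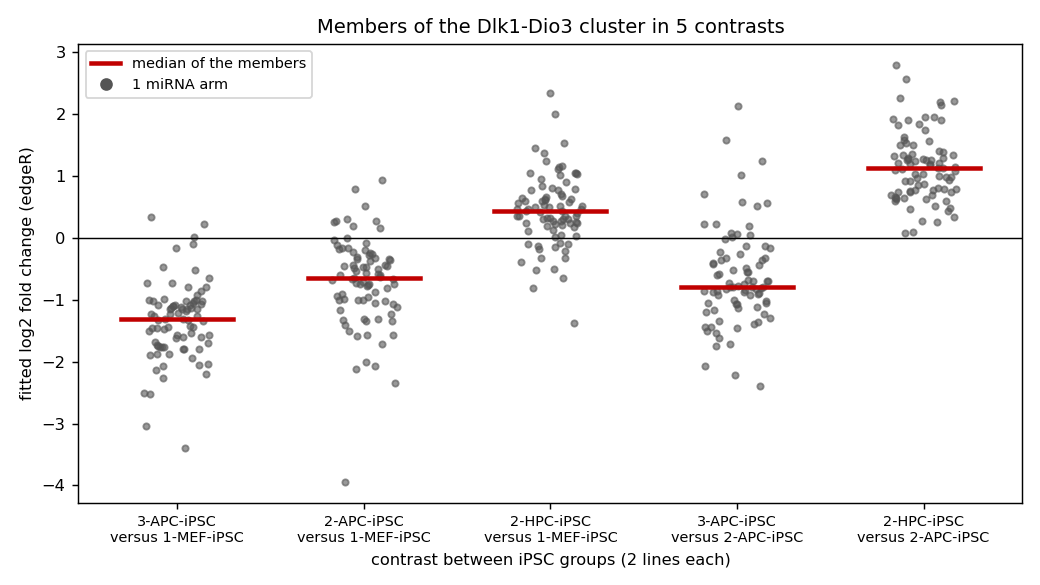
Log2 fold change (vertical axis) of each tested Dlk1-Dio3 feature in the 5 contrasts of iPSC groups (horizontal axis), 1 point per feature and a line at the median, n = 2 libraries per group. In 3-APC-iPSC against 1-MEF-iPSC 80 of 83 features lie below 0, and in 2-HPC-iPSC against 2-APC-iPSC all 83 lie above 0.

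In 3-APC-iPSC against 1-MEF-iPSC the single miRNAs nearest to the threshold also lay in this cluster. Mir494-3p (110953528 to 110953612) stood at 133 and 12.8 CPM in 1-MEF-iPSC and 3-APC-iPSC (n = 2 each, log2 fold change -3.40, SE 0.602, edgeR adjusted p 0.0693, DESeq2 3.86e-06). Mir323-3p (110950718 to 110950803) stood at 38.3 and 6.79 CPM (-2.51, SE 0.447, edgeR adjusted p 0.0693, DESeq2 1.54e-05) and Mir369-3p (110981628 to 110981706) at 393 and 48.4 CPM (-3.04, SE 0.587, edgeR adjusted p 0.0873, DESeq2 2.23e-05). The Sfmbt2 cluster was higher in 47 of 52 features (median 0.80, camera adjusted p 4.55e-07, 0.910 with an estimated correlation), but 0.09 (adjusted p 0.567) without line 42 and 2.57 without line 37. Mir669c-5p of that cluster stood at 1677 and 3560 CPM (1.09, SE 0.924). The miR-302 cluster had a median of 0.97 (adjusted p 0.0141, 0.910 with an estimated correlation), and 0.19 (0.711) without line 42, 0.54 (0.178) without line 9 and 3.14 without line 37. Mir302b-3p stood at 1408 and 2999 CPM (1.12, SE 0.887).

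Line 37 also decided which other lists passed in that contrast. Without it let-7 (1.88, adjusted p 0.000163), the mesenchymal list (1.49, 1.68e-05) and the haematopoietic list (1.20, 0.0493) passed, and without line 42 the mesenchymal list passed the other way (-0.79, 9.02e-05). With all lines the mesenchymal median was -0.11 while the test pointed up (adjusted p 0.673), and the miR-290, neural and muscle medians were 0.06, 0.22 and 0.18 with means of -0.24, -0.05 and -0.01. The haematopoietic list had 1 feature higher when adjusted over the list alone. The mesenchymal and the endothelial, hepatic and endocrine medians changed sign with scaling. edgeR called 0 of 744 features, with 86 at unadjusted p under 0.05, and DESeq2 called 35 (1 higher, 34 lower). Without line 37 edgeR called 81 (50 higher, 31 lower). Total-count scaling moved the median of all features from -0.00 to 0.20.

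In 2-APC-iPSC against 1-MEF-iPSC the miR-302 cluster stood higher and the mesenchymal and let-7 miRNAs lower, and the miR-290 median was -0.26 (camera adjusted p 0.230). Mir302b-3p stood at 6146 against 1408 CPM (2.07, SE 0.912) and Mirlet7f-5p at 5596 against 9276 CPM (-0.85, SE 0.605), n = 2 each. The miR-302 list had a median of 1.72 (camera adjusted p 2.79e-05, 0.523 with an estimated correlation), and 3.92 without line 37, 1.02 without line 32 and 1.00 without line 42. The Sfmbt2 list had 0.84 (1.25e-08, 0.523 with an estimated correlation), and 0.05 (0.399) without line 42 and 2.53 without line 37. The miR-17 list had 0.47 (0.000353, 0.379 with an estimated correlation), with 0.70 without line 37 and 0.72 without line 32. The Fmr1-side list had 0.53 (0.00944, 0.523 with an estimated correlation), with 0.53 (0.397) without line 37 and 0.25 (0.312) without line 32.

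The mesenchymal list had 30 of 31 features negative in that contrast (median -1.58, camera adjusted p 1.18e-08, 0.523 with an estimated correlation), but 0.07 (0.445) without line 37. The let-7 list had a median of -1.01 (0.00944, 0.523 with an estimated correlation), and 0.59 (0.659) without line 37, -0.49 (0.392) without line 32, -1.68 without line 42 and -1.54 without line 4. The striated muscle list had 1.89 (0.0240, 0.379 with an estimated correlation), with 2 features higher when adjusted over the list alone, and 2.26 (0.0851) without line 37 and 0.88 (0.146) without line 4. The miR-290 list passed without line 37 (-0.41, 0.0207) and the miR-34 list without line 42 (-1.21, 0.0201), and the miR-290 and epithelial medians changed sign with scaling. The features nearest to the threshold were Mir206-3p (4.33, SE 0.833, edgeR adjusted p 0.255), Mir341-3p (-2.11, 0.294) and Mir210-3p (-2.57, 0.294). edgeR called 0 of 744, with 97 at unadjusted p under 0.05, and DESeq2 called 18 (5 higher, 13 lower). Without line 37 edgeR called 32 and without line 42 it called 30. Total-count scaling moved the median of all features from -0.10 to 0.13.

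In 2-HPC-iPSC against 1-MEF-iPSC the imprinted clusters stood higher. The Sfmbt2 list had a median of 0.67 (camera adjusted p 4.30e-08, 0.865 with an estimated correlation), and 0.12 (0.803) without line 42 and 2.42 without line 37. The other imprinted loci had 0.73 (0.0381, 0.522 with an estimated correlation), and 1.22 (0.160) without line 37 and 0.44 (0.0719) without line 16, with Mir335-3p at 279 against 162 CPM (0.73, SE 0.443). The epithelial list had a median of -0.59 (0.00524, 0.522 with an estimated correlation), and -0.34 (0.0576) without line 37 and -0.25 (0.0821) without line 42, with Mir182-5p at 192691 against 297372 CPM (-0.69, SE 0.470). The Fmr1-side, endothelial, miR-34 and muscle medians changed sign with scaling, the miR-290 median was 0.36 with a mean of -0.01, and the miR-17 median was 0.04 while its test pointed down.

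Single lines decided further lists in that contrast. Without line 37 the let-7 (1.51, adjusted p 0.00173), mesenchymal (1.63, 4.47e-06) and miR-302 lists (2.38, 0.00160) passed upward. Without line 42 they passed downward, let-7 at -0.54 (0.0108), mesenchymal at -0.52 (4.60e-07) and miR-302 at -0.43 (0.0389). Without line 16 the mesenchymal (0.56, 0.000223), miR-302 (0.88, 0.00605), miR-290 (-0.53, 2.26e-05) and Fmr1-side lists (-0.44, 0.0234) passed. The features nearest to the threshold were AC115697.1-5p (-4.49, SE 1.40), AC113316.1-5p (-4.11, SE 1.29) and Mir196a-3p (-1.89, SE 0.608), each with edgeR adjusted p 0.819, and the first 2 stood at 0.18 and 0.06 without line 42. edgeR called 0 of 744, with 38 at unadjusted p under 0.05, and DESeq2 called 1 lower. Without line 37 edgeR called 28. Total-count scaling moved the median of all features from 0.00 to 0.25.

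In 3-APC-iPSC against 2-APC-iPSC, both labelled as derived from adipose progenitor cells, mesenchymal and let-7 miRNAs stood higher. Mir21-5p stood at 55737 against 27136 CPM (1.15, SE 0.663) and Mirlet7f-5p at 13239 against 5596 CPM (1.36, SE 0.612), n = 2 each. The mesenchymal list had a median of 1.39 in 29 of 31 features (camera adjusted p 3.54e-12, 0.468 with an estimated correlation), with 7 higher when adjusted over the list alone. The let-7 list had 1.36 (1.94e-05, 0.478 with an estimated correlation), or 0.90 without line 32. The miR-17 list had -0.39 in all 20 features (0.00131, 0.257 with an estimated correlation), with -0.43 (0.0716) without line 4. The muscle list had -1.71 (0.00796, 0.257 with an estimated correlation), with 2 lower when adjusted over the list alone, and -0.71 (0.179) without line 4.

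The miR-302 list did not pass in that contrast with all lines (-0.89, adjusted p 0.108) but did without line 37 (-0.90, 0.0461), 42 (-0.89, 0.0474), 4 (-1.39, 0.0250) or 9 (-1.20, 0.0176), and the haematopoietic list did without line 4 (0.80, 0.0275). The miR-290 median changed sign with scaling, and the epithelial median was -0.03 with a mean of 0.03. The features nearest to the threshold were Mir323-3p (-2.21, edgeR adjusted p 0.187), AC084162.1-5p with 11 other names (4.49, at 7.35 against 0.329 CPM, near the floor in 2-APC-iPSC) and Mir145-5p (2.40). edgeR called 0 of 744, with 73 at unadjusted p under 0.05, and DESeq2 called 7 (3 higher, 4 lower). Without line 37 edgeR called 12 and without line 42 it called 13. DESeq2 size factors moved the median of all features from -0.04 to -0.14.

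In 2-HPC-iPSC against 2-APC-iPSC the mesenchymal and let-7 miRNAs stood higher and the miR-302 cluster lower, and the miR-290 median was 0.18 (camera adjusted p 0.537). Mir143-3p stood at 67479 against 34210 CPM (1.05, SE 0.525) and Mir302b-3p at 1998 against 6146 CPM (-1.62, SE 0.899), n = 2 each. The mesenchymal list had a median of 1.82 (camera adjusted p 1.56e-10, 0.446 with an estimated correlation), with 6 higher when adjusted over the list alone, or 1.09 without line 18. The let-7 list had 1.28 (0.000593, 0.446 with an estimated correlation), and 0.58 (0.159) without line 32 and 0.90 (0.0666) without line 18. The miR-17 list had -0.53 (0.000182, 0.172 with an estimated correlation), or -0.32 without line 18. The miR-302 list had -1.39 (0.000628, 0.446 with an estimated correlation), and -0.65 (0.162) without line 32 and -1.07 (0.0616) without line 16.

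The Fmr1-side list in that contrast had -0.74 (0.000628, 0.446 with an estimated correlation), and -0.46 (0.0934) without line 32 and -0.47 (0.0970) without line 18. The muscle list had -2.13 (0.00258, 0.172 with an estimated correlation), with 2 lower when adjusted over the list alone, and -1.10 (0.0816) without line 4. The miR-290 list passed without line 18 (0.58, 0.00304). The features nearest to the threshold were Mir145-5p (2.36), Mir341-3p (2.15) and Mir206-3p (-3.56, SE 0.803, edgeR adjusted p 0.269). edgeR called 0 of 744, with 92 at unadjusted p under 0.05, and DESeq2 called 17 (12 higher, 5 lower). Without line 37 edgeR called 15 and without line 42 it called 20.

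miRNAs typical of the founder cells were followed into the iPSC of haematopoietic origin. Of 18 features at least 8-fold above the other somatic libraries in 2-HPC, 14 could be tested. Mir223-3p, Mir223-5p, Mir451-5p and Mir144-3p stood at 356 to 40038.5 CPM in 2-HPC. In lines 16 and 18 these stood at 0 to 0.193 CPM, too low to be tested. The 14 tested features had a median of -0.26 against 2-APC-iPSC (camera adjusted p 0.212, 0.467 with an estimated correlation) and 0.00 against 1-MEF-iPSC (0.879). The 59 features enriched in the fibroblast and adipose libraries stood higher in 2-HPC-iPSC than in 2-APC-iPSC, with 55 positive (median 1.28, adjusted p 4.67e-18, 0.0589 with an estimated correlation). When adjusted over the list alone 12 were higher and 1 lower, against 0 over all features. Against 1-MEF-iPSC 45 were positive (median 0.31, adjusted p 0.000497, 0.490 with an estimated correlation). Of the 59 features 32 were Dlk1-Dio3 members. The other 27, set apart after values were seen, had a median of 1.28 against 2-APC-iPSC (23 positive, adjusted p 3.10e-05, 0.467 with an estimated correlation) and 0.14 against 1-MEF-iPSC (18 positive, adjusted p 0.167). Mir143-3p and Mir21-5p of the mesenchymal list were among these 27, and the mesenchymal list had a median of 1.82 against 2-APC-iPSC. The lists were chosen on the 4 somatic libraries, which these contrasts do not use.

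Along the number in the title, over all 8 lines and in part confounded with origin, no feature passed with edgeR, and those with the lowest adjusted p follow. Upward, Mir142-5p changed by 1.28 per step (edgeR adjusted p 0.290), and Mir205-5p (0.64), Mir301-5p (1.18), AL844882.1-5p (0.87) and a joint feature of AC151577.1-3p and AL603804.1-3p (1.21) had adjusted p of 0.473, and Mir142-3p 0.65 (0.570). Downward were Mir369-3p (-1.53), Mir494-3p (-1.70), AC115697.1-5p (-2.76), AC113316.1-5p (-2.33), Mir183-3p (-0.92) and Mir690-3p with 17 other names (-1.66), each with adjusted p 0.290. The Sfmbt2 list had a median of 0.40 (camera adjusted p 5.19e-08, 0.889 with an estimated correlation), and 0.05 (0.912) without line 42 and 0.74 without line 37. The miR-302 list had 0.48 (0.0215, 0.889 with an estimated correlation), and 0.00 (0.912) without line 42, 0.41 (0.0681) without line 16, 0.55 (0.0794) without line 9, 0.73 without line 37 and 0.79 without line 3. Without line 37 the let-7 (0.72, 0.000708), mesenchymal (0.53, 6.61e-05) and haematopoietic lists (0.44, 0.0252) passed. The mesenchymal and endothelial medians changed sign with scaling, the mesenchymal median was -0.02 while its test pointed up, the muscle median was 0.09 while its test pointed down, and the miR-290 and neural medians were 0.02 and 0.13 with means of -0.13 and -0.03. edgeR called 0 of 695, with 57 at unadjusted p under 0.05, DESeq2 called 11 (1 higher, 10 lower), and edgeR called 2 without line 18.

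The number of lists passing camera at the preset correlation was 3, 8, 4, 5 and 7 in the 5 contrasts as given and 3 along the number in the title, and 0 in each with an estimated correlation. fry passed 1 list in 3-APC-iPSC against 1-MEF-iPSC and 0 in the others. In fits that leave 1 library in a group, that lone sample is assumed to vary like the other groups.

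The ESC library, which differed in strain and passage, was set beside the range of the 8 iPSC lines without a test. Mir291b-5p of the miR-290 cluster stood at 4.71 CPM in ESC against at least 204 CPM in iPSC (log2 ratio -5.17), and Mir146b-5p, a miRNA of immune signalling, at 10789 against at most 2813 CPM (1.94). AC115697.1-3p stood at 5306 against at most 1267 CPM (2.07). The next features above were joint features of Mir2134-3p and Mir689-3p (1.79) and of AC140318.1-5p and AC165092.1-5p (1.70), and CT009696.2-5p (1.52). The next below were Mir291b-3p (-1.39), Mir1186-5p (-1.30), Mir141-3p (-0.79) and Mir1965-3p (-0.71). At 50 CPM or more 66 features lay above every iPSC line and 20 below. ESC lay outside all 8 iPSC lines in 5 lists, with 6.85% let-7 reads (iPSC 0.819 to 4.69%), 3.48% miR-290 (3.98 to 7.29%), 29.8% epithelial (30.7 to 61.2%), 2.51% miR-17 (2.81 to 5.01%) and 2.55% miR-34 (0.483 to 2.29%). It lay inside their range in the other 10, among them 19.6% mesenchymal and 13.3% Dlk1-Dio3 reads, and Mir182-5p took 20.5% (20.4835 to 20.5381).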

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

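In this part the tests on other splits, on tag length, on 3′ ends, on the Dlk1-Dio3 list and on Mir143-3p with Mir21-5p were chosen only after the result was seen. Of 92 groups examined for a single library far from the others 19 had one, and chance alone gives about 5%.

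The first pattern is the 517 features called between iPSC and somatic libraries. Of 100 splits of the 12 libraries into 8 and 4, only the real 1 gave as many, and the highest other gave 83. Every other split mixes iPSC with somatic libraries in its larger group, which widens the spread there. The splits therefore show a strong division between these libraries but cannot exclude chance or a division by library set. A narrower size range of somatic libraries as the whole cause is argued against, since with tags of 21 to 23 nt alone 95.8% of the called features that could be tested (429 of 448) kept their call and direction. A difference in library preparation or trimming stays open and could contribute, because 2-HPC shared 3′ ends with the fibroblast and adipose libraries 28.4 percentage points more often than iPSC did, although it is another cell type. A difference between pluripotent and somatic cells, which the design names, cannot be told apart from such a library set.

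The second pattern is the lower Dlk1-Dio3 list in 3-APC-iPSC. Fewer mesenchymal cells in those cultures than in 2-APC-iPSC is argued against, since the mesenchymal list had a median of 1.39 against 2-APC-iPSC. Fewer such cells than in 1-MEF-iPSC stays open, since the mesenchymal list had a median of -0.11 against 1-MEF-iPSC but of -0.79 without line 42 and 1.49 without line 37, where the Dlk1-Dio3 median was -0.81. TMM scaling is argued against by a median of -1.11 with total counts, and the unlike line 42 by a median of -1.54 without it. A lower expression of the cluster in these lines is only a hypothesis, and differences between single lines stay open, since the list's adjusted p with an estimated correlation was 0.0623.

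The third pattern is the abundance of Mir143-3p and Mir21-5p in iPSC libraries. Whether an admixture of cells like the fibroblast or adipose libraries was the main source of both was not settled. For Mir143-3p the lowest iPSC share was 2.99 times the highest somatic share, but the ratio was 1.28 with TMM scaling. The test therefore could not tell. For Mir21-5p the ratio of shares was 0.516, which such an admixture allows. In every iPSC library, however, Mir21-5p held more reads than the let-7 list (1.86% against 0.844% in line 42, the lowest). That list leaves out the joint feature of Mirlet7a-5p and CT009696.1. In fibroblast and adipose libraries Mir21-5p held 3.34 to 3.61% against 43.0 to 63.2% for the list. This goes against such cells as the main source of Mir21-5p. Mir143-3p was mostly 20 nt in iPSC (89.2 to 92.8% of its reads) and 21 nt in those libraries (66.8 to 69.2%). Unlike counting in the library sets could therefore still bear on these values. ESC held 7.58% Mir143-3p and 10.5% Mir21-5p. A second cell population whose share differs between iPSC cultures stays open and could be present, as let-7 and mesenchymal totals went together over the 8 lines (Pearson r 0.922). Feeder cells or differentiating cells were not sampled here.

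The fibroblast library stood apart in 3 sums. Its miRNA share was 72.8% of reads, against 68.3 to 68.8% in the other somatic libraries. Its striated muscle list held 327439 CPM, against 663 to 9743. Its list of other imprinted loci held 8654 CPM, against 1316 to 1465.

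The haematopoietic library stood apart in several miRNAs. Its haematopoietic list held 66636 CPM (others 189 to 303) and Mir223-3p 40038.5 CPM (8.62 to 32.2). Its miR-17 list held 28758.7 CPM (3604 to 6754). The joint feature of Mir103-3p and Mir107-3p held 14078 CPM (2339 to 2506) and Mir107-3p alone 6908 CPM (1287 to 1370). Mirlet7i-5p was lower there, at 30219 CPM (45941 to 48115). The miR-17 list changed by -0.44 on the log2 scale from 2-HPC to the mean of its 2 iPSC lines, whereas it changed by 1.90 to 3.36 from the other sources. With total-count scaling the change from 2-HPC was 0.90, against 2.98 to 4.87 from the other sources, so its sign depends on the scaling. The difference between sources was not tested.

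Traces of the miR-290 cluster were seen in 2-APC, with 2.28 CPM for the list (0 to 0.328 in the other somatic libraries) and 0.228 CPM, or 1 read, for each of Mir293-5p and Mir291a-5p (0 in the others).

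Among iPSC lines, line 42 was high in Mir291a-3p (3594 CPM, others 610 to 1548), Mir293-3p (13608 CPM, others 4459 to 6377) and Mir295-3p (12911 CPM, others 4064 to 6546). Line 16 was high in Mir291a-5p (3161 CPM, others 939 to 1813). Line 4 was high in the striated muscle list (8761 CPM, others 216 to 1785). Line 32 was high in the endothelial, hepatic and endocrine list (21014 CPM, others 2811 to 9336). Line 3 was high in the haematopoietic list (619.9 CPM, others 162 to 372).

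Of 16 tags outside the annotated small RNAs 10 were more common in every iPSC library than in any somatic library, and 6 were not. These 6 were 5 forms of let-7 with added A, such as 1 of Mirlet7f-2 (1.31 to 3.38% in somatic and at most 0.102% in iPSC libraries), and a 22 nt tag at chromosome 17, 17967330 to 17967351 (0.0617 to 2.91% and at most 0.0717%). The 22 nt tag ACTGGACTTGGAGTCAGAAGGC, with 1 genome match (chromosome 18, 61557491 to 61557512), reached 5.26% of reads (5.24968 to 5.27048) and at most 0.0597% in somatic libraries. A 20 nt tag of the mitochondrial genome (16169 to 16188) reached 1.14%. A 28 nt tag with 11 genome matches, the first at chromosome 1, 172975116 to 172975143, reached 2.00%. The annotation lacks some known miRNAs, among them let-7e and miR-378a. The 22 nt tags on chromosomes 17 and 18 may therefore be known miRNAs. A form of Mir143 with an added T reached 1.70% and a form of Mir183 with an added A reached 1.09%.

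Other such tags had no match in the genome. They were of 28 nt (7.88% at most), 27 nt (2.78%), 28 nt (1.24%) and 30 nt (1.49%), each with 0 reads counted in somatic libraries, and of 25 nt (0.369% in line 42 and 1.07% in ESC). Their source was not tested, and tags counted fewer than 10 times in a library were not read for this list.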

How the results depend on the processing

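The tests with Mir-named hairpins alone, with tags of 21 to 23 nt alone, with founder lists without Dlk1-Dio3 members, and the list tests with total counts or with a library left out were chosen only after the data were seen. The cause was not tested for any change below unless it is stated.

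The 517 features called between iPSC and somatic libraries stayed within 1.5 times under every alternative run. Counts ranged from 382 (Mir-named hairpins alone, of 530 tested) and 388 (hairpins, of 519) to 682 (no filter, of 2110), and from 494 to 592 with a library left out, where 592 without 2-HPC held 357 higher and 235 lower. It was 412 with shared tags left out, 497 with tags counted at least 2 times, 471 with tags of 21 to 23 nt, 541 with a source block, 528 with ESC counted as iPSC, 518 with DESeq2 size factors and 515 with total counts. Without 2-HPC Mir142-5p reversed to 2.06. Of 546 alternative values of the 24 named miRNAs 545 kept their direction and side of the threshold, and Mir223-3p got no p from DESeq2.

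Counts in the contrasts of iPSC groups and along the number in the title were 0 with edgeR. The order below is 3-APC-iPSC, 2-APC-iPSC and 2-HPC-iPSC against 1-MEF-iPSC, then 3-APC-iPSC and 2-HPC-iPSC against 2-APC-iPSC, then the number in the title. The DESeq2 test called 35, 18, 1, 7, 17 and 11. Without a filter edgeR called 15, 23, 5, 8, 19 and 15. With shared tags left out the first gave 3, and Mir-named hairpins alone gave 3 in the first and 1 in the second. With the spread of the compared groups alone 3-APC-iPSC against 2-APC-iPSC gave 1 and 2-HPC-iPSC against 2-APC-iPSC gave 22. With a library left out the counts ranged over 0 to 81, 0 to 32, 0 to 28, 0 to 13, 0 to 20 and 0 to 2. The upper ends came without line 37 in the first 3, without line 42 in the next 2 (12 and 15 without line 37, and 30 in the second without line 42), and without line 18 in the last. Total counts and DESeq2 size factors gave 0 in all 6.

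Lists passing camera at the preset correlation numbered 10 in iPSC against somatic libraries and 3, 8, 4, 5, 7 and 3 in the order above. With an estimated correlation 0 passed in each of the 7, since the estimate adds the spread shared by members of a list. fry passed 1 list in the first contrast and 0 in the other contrasts and along the number in the title, and 11 in iPSC against somatic libraries. With a library left out the number ranged over 9 to 12 in iPSC against somatic libraries, then 2 to 6, 5 to 8, 3 to 7, 5 to 6, 4 to 7 and 1 to 6.

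Directions reversed with scaling in 13 list medians, of which 0 passed camera in their comparison. The Dlk1-Dio3 median of iPSC against somatic libraries was 0.26 with total counts and that of the other imprinted loci 0.86. The rise or fall of let-7, mesenchymal and miR-302 lists in 2-HPC-iPSC against 1-MEF-iPSC followed the line left out, with 1.51, 1.63 and 2.38 without line 37 and -0.54, -0.52 and -0.43 without line 42. In 2-APC-iPSC against 1-MEF-iPSC the let-7 median ranged from -1.68 (without line 42) to 0.59 (without line 37) and the mesenchymal median from -2.05 to 0.0735 (without the same lines). In 2-HPC-iPSC against 1-MEF-iPSC AC115697.1-5p ranged from -6.20 (without line 18) to 0.180 (without line 42) and AC113316.1-5p from -5.70 to 0.0622 (without the same lines). Features enriched in 2-HPC reversed against 1-MEF-iPSC with a 4-fold list (adjusted p 0.730), and those enriched in fibroblast and adipose libraries had adjusted p 0.167 against 1-MEF-iPSC without Dlk1-Dio3 members and adjusted p of 0.0589 against 2-APC-iPSC and 0.490 against 1-MEF-iPSC with an estimated correlation.

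Depth limited features near the floor of 3 counts, which stood at 0.2005 to 0.685 CPM.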

Other observations

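The test relating let-7 to the mesenchymal list was chosen only after the result was seen, and no further test is reported in this part.

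Line 37 of 1-MEF-iPSC held 4.29% let-7, 21.7% mesenchymal and 33.8% epithelial reads, and ESC held 6.85%, 19.6% and 29.8%. Line 42 held 0.844%, 4.93% and 61.2%. Lines with more let-7 also held more mesenchymal reads (Pearson r 0.922 over 8 lines), which may reflect a share of cells leaving pluripotency, but the miR-290 cluster took 3.98 to 7.29% in all 8 lines and no marker of such cells other than miRNAs was analysed here.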
